A study of Homo sapiens with 4 samples.

How the data were processed

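Total RNA from HCE cells, which the labels call an undifferentiated cell line, was measured on 4 whole-transcript arrays, 2 from cells transfected with a scramble control siRNA pool and 2 from cells transfected with an siRNA pool against KLF7 (siKLF7). Per the labels' protocols, 100000 cells were plated per well, siRNA was used at 20 nM, and cells were collected 48 hours after transfection. The groups and replicate numbers were taken from the sample labels. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

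The authors deposited 1 table of array intensity values on a linear scale. Per the submitters' processing notes, these values were made with Affymetrix Expression Console 1.1.1 and PLIER 2.0. Whether the arrays were also normalized to each other is not given in the sources used here. The median deposited signal was 187, 194, 190 and 185 for scramble control replicates 1 and 2 and siKLF7 replicates 1 and 2. A shift in array scale would move all genes together, and the pseudocount shrinks fold changes of dim genes.

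The table held 33297 features. A table of platform annotation gave 1 gene symbol for 19460 features and several for 1754, and 12083 features had no listed gene. Features with 1 symbol were used, and for the 769 genes with several features the one with the highest mean was taken, which left 18417 genes. The 13837 other features were tested separately by limma, and 0 passed the threshold with 4 arrays (646 at an unadjusted p under 0.05) or with 3 arrays (373 at an unadjusted p under 0.05). No genome reference was used, and no coordinates are given.

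Values were analysed as log2(signal + 16) without further normalization or a filter on dim genes. The comparison, siKLF7 minus scramble control, was fitted with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.63 prior degrees of freedom. With 2 arrays per group, the number of arrays limits the precision.

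Before the data were examined, 30 gene lists were fixed, covering epithelial differentiation, cell cycle, signalling, stress, metabolism and markers of other cell types. Of their 802 written members, 737 were matched to the array, 45 of them through an older symbol. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with all other genes, and Benjamini-Hochberg adjustment was over the 30 lists. List medians were also set against 10000 random lists matched on mean level, and intervals of list medians were bootstrapped over genes at 95%.

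The rule for naming genes was also fixed before the data were examined. KLF7 and KLF4 were always named. Up to 10 genes in each direction were taken by fold change among those that passed with non-overlapping groups, and empty places were filled by unadjusted p among genes with a log2 change of at least 0.585 and non-overlapping groups. Up to 4 members with the smallest limma p were taken from each list described, and genes named outside this rule are said to be so. Genes on the Y chromosome, other genes that mark a donor, and placeholder symbols were never named. A check for mixed-up samples found 1 array that did not match the others.

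A second fit without scramble control replicate 1 was planned as one of the leave-one-out alternatives. It was reported beside the first, with the same naming rule, after the data were seen, because that array stood apart from the other 3. This fit of 3 arrays had 1 residual degree of freedom and 74.2 prior degrees of freedom. Its spread came only from the siKLF7 pair, and the lone control was assumed to vary alike.

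Both fits were tested on simulated data with 100 genes changed by a log2 change of 1 and 100 by 2 among the 18417. Noise followed each gene's own fitted spread with 4 arrays, and the spread after shrinkage to the prior with 3 arrays. The 3-array simulation also gave the lone control the spread of the siKLF7 pair, so it met that fit's assumptions. The recoveries of the fits can therefore not be compared. With 4 arrays, 6% of the former and 54% of the latter were recovered, and 2 unchanged genes were called. With 3 arrays, 100% of both were recovered, and 11 unchanged genes were called. A list shifted by 0.4 was recovered with either, and 0 other lists were called. The simulated noise was independent between genes, so this does not test false calls of lists whose genes vary together.

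The alternatives were quantile normalization, median centring, leaving out the dimmest 25% or 50% of genes, a prior with no trend or a robust one, the mean of a gene's features, a pseudocount of 1 or 32, an adjusted p under 0.10, the replicate number as a block, and leaving out each array. Figures were drawn with matplotlib 3.10.9.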

Results

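The series examined KLF7, a zinc finger transcription factor, by siRNA knockdown in HCE cells, in a study of the corneal epithelium. Expression of 18417 genes was measured in 2 scramble control and 2 siKLF7 arrays. The siKLF7 arrays correlated with each other at r = 0.994 across genes, and with scramble control replicate 2 at 0.990 and 0.992. Scramble control replicate 1 correlated with the other arrays at 0.934 to 0.938. In that array, 551 genes were at least 2-fold lower and 389 at least 2-fold higher than the mean of the other 3, against 14 genes at least 2-fold apart between the siKLF7 arrays. Members of the corneal epithelial differentiation list had a median of -3.47 (log2) in scramble control replicate 1 against the mean of the other 3, and 30 of 38 were at least 2-fold lower there. Whether that array came from the same cells as the other 3 is open. Values are therefore given with all 4 arrays and with 3 arrays, without scramble control replicate 1.

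**Figure D1:**
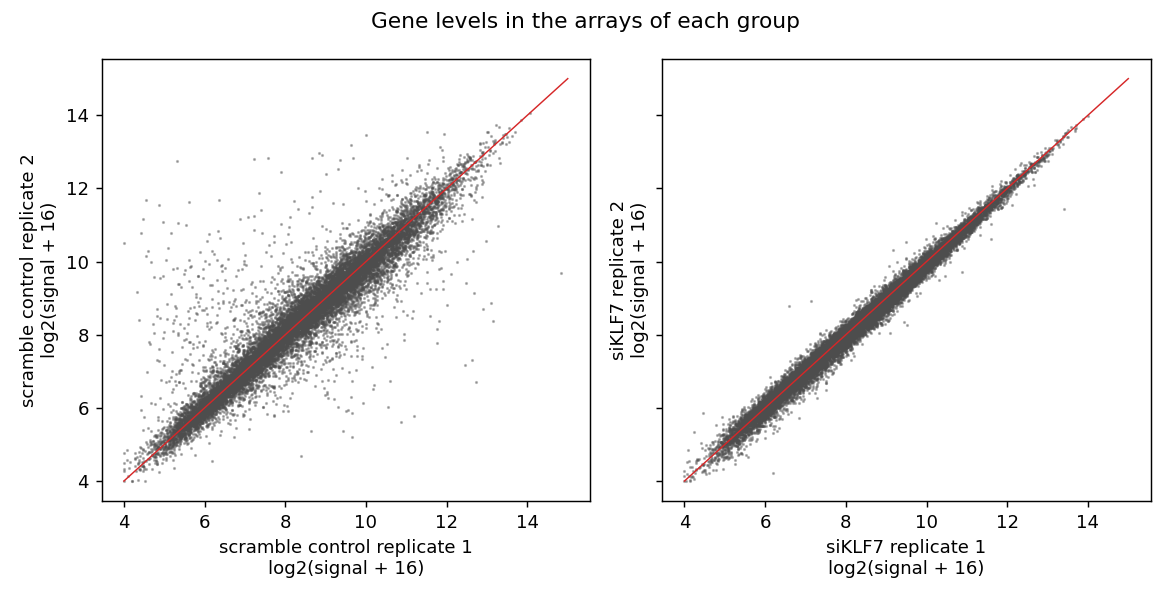
Each point is a gene, at its log2(signal + 16) in the arrays of 1 group, with the line of equal levels in red. The scramble control arrays had 975 genes at least 2-fold apart and the siKLF7 arrays had 14; genes that mark a donor were left out of the plot.

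The targeted gene was measured first. KLF7 stood at log2 levels of 12.19 and 11.52 in the scramble control arrays and 10.56 and 10.15 in the siKLF7 arrays. The mean signal was 3780 ± 1229 (SD, n = 2) in control and 1307 ± 262 (SD, n = 2) in siKLF7 arrays. The log2 change was -1.50 (SE 0.28), or 35.5% of the control level, and limma's adjusted p was 0.639. An exact two-sided permutation test gave p = 0.333, the smallest that 2 arrays against 2 can give. With 3 arrays KLF7 fell, by 1.16 on the log2 scale (SE 0.13, adjusted p = 1.2e-09), to 44.8% of the level in scramble control replicate 2. KLF4, a related factor in epithelial differentiation, stood at 7.41 and 9.89 in the control arrays and 9.95 and 10.07 in the siKLF7 arrays. Its log2 difference was 1.36 (SE 0.83) with 4 arrays and 0.12 (SE 0.15, adjusted p = 0.79) with 3 arrays, and neither passed.

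**Figure D2:**
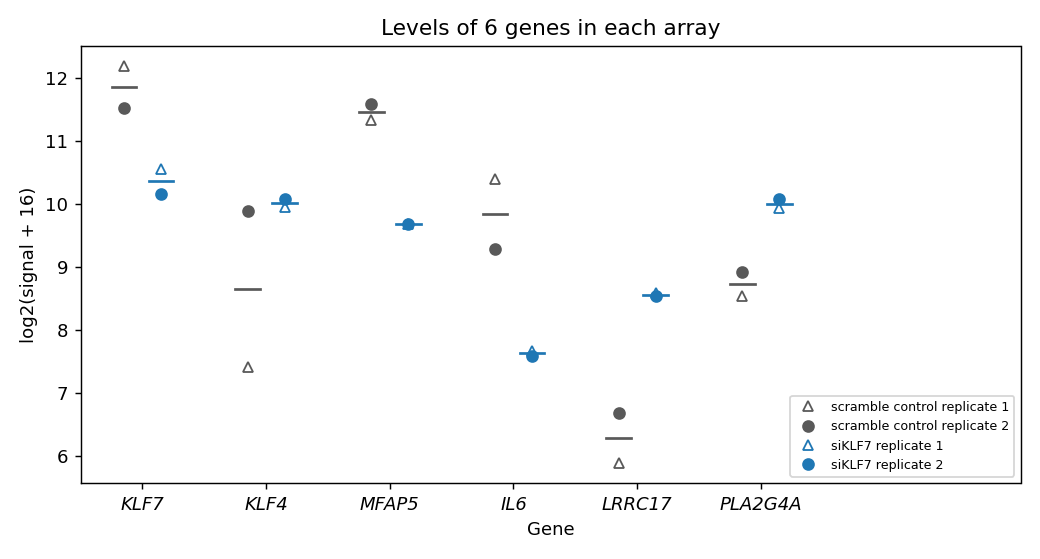
The log2(signal + 16) of 6 genes in each array is shown, with scramble control in grey, siKLF7 in blue, replicate 1 as triangles, replicate 2 as circles and group means as bars. KLF7, MFAP5 and IL6 were lower and LRRC17 and PLA2G4A higher in both siKLF7 arrays than in both controls, and none of these passed with 4 arrays.

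The main comparison asked which genes differed between siKLF7 and scramble control cells. MFAP5, a protein of extracellular microfibrils, was 3.42-fold lower in siKLF7 arrays (log2 -1.77, SE 0.14), and the cytokine gene IL6 was 4.62-fold lower (log2 -2.21, SE 0.38). HIRA, a histone chaperone, differed by -1.02 (SE 0.12), and LASP1, an actin-binding protein, by -1.25 (SE 0.21), or -0.67 with the mean of its features. LRRC17 was 4.85-fold higher (log2 2.28, SE 0.28), and PLA2G4A, the cytosolic phospholipase A2 that releases arachidonic acid, was 2.41-fold higher (log2 1.27, SE 0.19). NTRK2, a neurotrophin receptor, differed by 0.76 (SE 0.11), and IVNS1ABP by 0.91 (SE 0.13). None of these passed with 4 arrays, and their adjusted p was 0.639. With limma, 0 genes passed and 1069 had an unadjusted p under 0.05, 350 higher and 719 lower. The groups did not overlap for 45.2% of genes, against 33.3% for a gene whose arrays fall in random order. Genes of 1 array can shift together, so the higher share is not a test of a knockdown effect. With the fold minimum of the naming rule, both siKLF7 values lay above both controls for 340 genes and below for 241. The remaining genes of the naming rule ranged from 0.69 for KIF15, a mitotic kinesin, to 1.32 for DIAPH2-AS1 among those higher, and from -0.66 for PRAMEF2, of a multigene family whose copies an array may not separate, to -1.09 for MFHAS1 among those lower. The count was 290 without scramble control replicate 1 and 4935 without scramble control replicate 2.

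With 3 arrays, 163 genes rose and 127 fell against scramble control replicate 2. LRRC17 rose by 1.88 (log2, SE 0.16, adjusted p = 1.4e-14), KIT, a receptor tyrosine kinase, by 1.77 (SE 0.16, adjusted p = 3.2e-13), and SLITRK6 by 1.63 (SE 0.15, adjusted p = 7.3e-13). PLA2G4A rose by 1.08, the desmosomal cadherin gene DSC1 by 1.14 and ABI3BP by 1.19. MFAP5 fell by 1.89 (SE 0.14, adjusted p = 1.1e-17) and IL6 by 1.66 (SE 0.16, adjusted p = 2.1e-12). S100A7, CRCT1, SPRR2D and LCE3D fell by 1.57, 1.39, 1.09 and 1.09, but their level in scramble control replicate 1 was not above both siKLF7 arrays, and with 4 arrays they stood at -0.43, 0.28, 1.95 and 0.03. SELENOP rose by 1.39 and DPP4 by 1.20, but neither gene was above both controls in both siKLF7 arrays (-0.41 and 0.64 with 4 arrays). SLITRK6, DSC1 and KIT stood at 2.68, 2.58 and 2.59 with 4 arrays. The KIT signal in scramble control replicate 1 was 17.2, near the pseudocount of 16. MTND2P28, a pseudogene of a mitochondrial gene, fell by 1.11 (-0.10 with 4 arrays), and its siKLF7 arrays stood at 13.41 and 11.43. Among all 18417 genes, both siKLF7 arrays lay on the same side of scramble control replicate 2 for 13685, and of both controls for 8320. Of the 290 genes, 183 had both siKLF7 arrays on the same side of both controls. Median centring gave 326 genes higher and 135 lower. Treating either siKLF7 array as the lone array gave fewer genes. The spread then came from scramble control replicate 2 and 1 siKLF7 array, with 35 or 37 genes at least 2-fold apart. The siKLF7 pair had 14, so these splits do not tell how many genes would be called with no effect.

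Against scramble control replicate 2 alone, with 3 arrays, 12 of 39 genes of G2/M and mitosis rose, and 23 when adjusted over the list alone. CCNB2 and CCNB1, mitotic cyclins, rose by 0.62 (SE 0.15) and 0.61 (SE 0.15), TTK, a spindle checkpoint kinase, by 0.68 (SE 0.16) and TOP2A, a DNA topoisomerase, by 0.58 (SE 0.14). The list median was 0.39 with 3 arrays (camera adjusted p = 2.8e-28) and 0.31 with 4 arrays (adjusted p = 1.8e-12). The adjusted p with an estimated correlation was 0.88 with 3 arrays and 0.64 with 4 arrays. With 4 arrays, 0 of 39 members passed over all genes or adjusted over the list alone. Without scramble control replicate 2 the median was 0.15. Members were above scramble control replicate 2 in 39 of 39 cases and above scramble control replicate 1 in 25 of 39. The control arrays differed from each other by a list median of 0.29.

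The G1/S and DNA replication list had a median of 0.16 with 4 arrays (camera adjusted p = 0.0003) and 0.16 with 3 arrays (adjusted p = 0.00017). The adjusted p with an estimated correlation was 0.64 and 0.88, and without scramble control replicate 2 the median was 0.10 and the call was lost (adjusted p = 0.056). With 3 arrays 1 of 38 members rose, also 1 adjusted over the list alone. That gene, CCNE2, a cyclin of the G1/S transition, rose by 0.66 (SE 0.16; 1.03 with 4 arrays), while CCNE1 stood at -0.26 (SE 0.16; -0.43 with 4 arrays). Replication-dependent histones had medians of 0.29 (adjusted p = 1.1e-07, and 0.64 with an estimated correlation) and 0.12 (adjusted p = 0.0025, and 0.88), and 1 of 26 rose with 3 arrays, H1-1 by 0.71 (0.43 with 4 arrays). Cytosolic ribosomal protein genes had medians of 0.20 (adjusted p = 8.5e-08, and 0.64 with an estimated correlation) and 0.10 (adjusted p = 0.0073, and 0.88), with 0 of 32 members passing in either fit. With 3 arrays the ribosomal call was lost with quantile normalization (adjusted p = 0.073) and without the dimmest 50% of genes (adjusted p = 0.085), and the histone call without the dimmest 50% (adjusted p = 0.059). Without scramble control replicate 2 the ribosomal median was 0.36.

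The NF-kB and cytokine list had a median of -0.27 with 4 arrays (camera adjusted p = 0.00022) and -0.25 with 3 arrays (adjusted p = 4.8e-06). The adjusted p with an estimated correlation was 0.64 and 0.88, and 20 of 30 members were below both controls in both siKLF7 arrays. With 3 arrays, 3 members fell and 2 rose, and 7 fell and 2 rose adjusted over the list alone. IL6 fell by 1.66, SOD2, the mitochondrial superoxide dismutase, by 0.86 (SE 0.14) and CCL20, a chemokine, by 0.63 (SE 0.16), while CXCL10 rose by 0.64 (SE 0.17). With 4 arrays SOD2 stood at -0.43 and CCL20 at -1.23. With 4 arrays CXCL10 stood at -0.69, and scramble control replicate 1 lay 2.23 above the mean of the others. The SD of CXCL10 in the siKLF7 arrays was 0.58 (log2, n = 2), close in size to its rise of 0.64. Its SE of 0.17 drew mostly on the prior. The other that rose, PTGS2, was named after its value was seen and rose by 0.39 (0.12 with 4 arrays). CXCL8 stood at -0.33 (SE 0.16; -0.52 with 4 arrays) and did not pass. Over the same list scramble control replicate 1 lay 0.20 above the mean of the other arrays.

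**Figure D3:**
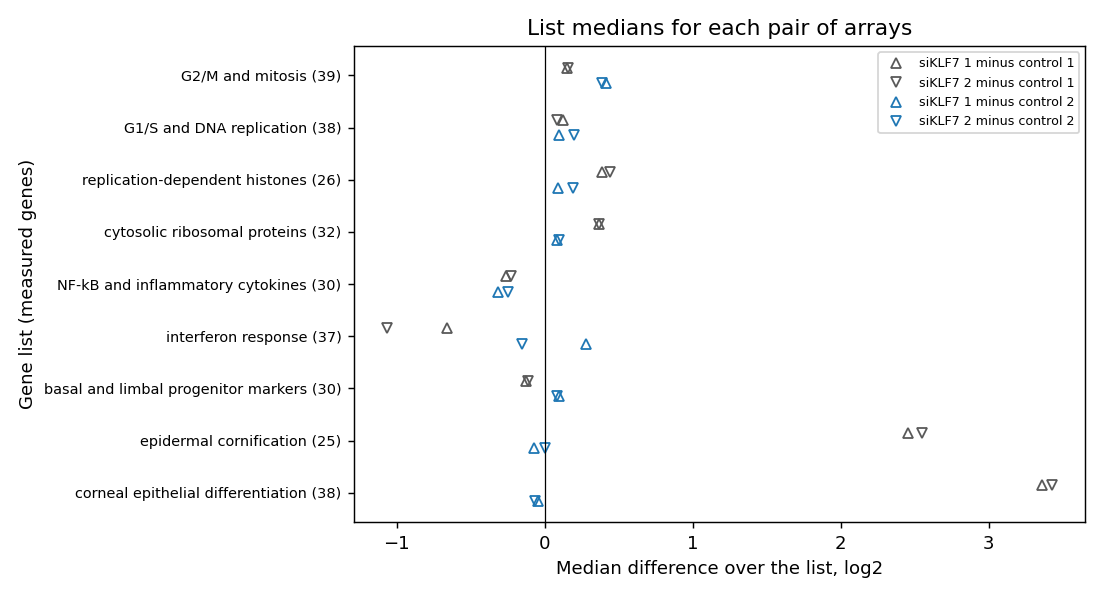
Each marker is the median log2 difference over a gene list between an siKLF7 array and a control array, grey against scramble control replicate 1 and blue against replicate 2. The medians of G2/M and mitosis genes lay between 0.15 and 0.41 for all 4 pairs, and those of corneal epithelial differentiation at 3.36 and 3.43 against replicate 1 and at -0.04 and -0.07 against replicate 2.

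Differentiation genes depended on the control array. Corneal epithelial differentiation genes had a median of 1.54 with 4 arrays (camera adjusted p = 1.1e-07, and 0.64 with an estimated correlation) and -0.07 with 3 arrays (adjusted p = 0.35). With 3 arrays, 6 of 38 rose and 7 fell, and 7 rose and 10 fell adjusted over the list alone. KRT12, a keratin of the corneal epithelium, rose by 0.81 (SE 0.12) and ALDH3A1, a corneal crystallin enzyme, by 0.65 (SE 0.15), while CNFN fell by 0.82 (SE 0.09), SPRR2D by 1.09 and S100P by 1.04. With 4 arrays KRT12 and ALDH3A1 stood at 2.93 and 2.53, and CNFN, SPRR2D and S100P had the opposite sign, at 1.98, 1.95 and 1.18. The SPRR2D signal in scramble control replicate 1 was 15.6, below the pseudocount of 16. Epidermal cornification genes had medians of 0.98 with 4 arrays (adjusted p = 2.3e-06, and 0.64 with an estimated correlation) and -0.03 with 3 arrays, where the mean was 0.01 and the test pointed up (adjusted p = 0.57). In that list 5 of 25 rose and 3 fell with 3 arrays, and 6 rose and 6 fell adjusted over the list alone. KRT10 rose by 0.94 (SE 0.09), CASP14 by 0.98 (SE 0.15) and DSC1 by 1.14, while LCE3D fell by 1.09. With 4 arrays these 4 genes stood at 4.28, 3.40, 2.58 and 0.03, and the signals of KRT10 and CASP14 in scramble control replicate 1 were below the pseudocount. With 4 arrays, 0 members of either list passed over all genes or adjusted over the list alone. Scramble control replicate 1 was lower by at least 2-fold for 18 of the 25 cornification genes. Differentiation regulators had medians of 0.44 (adjusted p = 0.0023, and 0.64 with an estimated correlation) and -0.08 (adjusted p = 0.55), and the 4-array call was also lost without the dimmest 50% of genes (adjusted p = 0.054). In that list PRDM1, a transcriptional repressor, fell by 0.78 (SE 0.16) with 3 arrays as 1 of 23 (2 fell adjusted over the list alone), and stood at -0.29 with 4 arrays.

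Basal and limbal progenitor markers differed between the fits. The list median was -0.02 with 4 arrays, where the mean was 0.11 and the test pointed up (camera adjusted p = 0.40). It was 0.11 with 3 arrays (adjusted p = 0.0015, and 0.88 with an estimated correlation), where 5 of 30 rose, and 8 adjusted over the list alone. KRT15, a basal keratin, rose by 0.85 (SE 0.13), GJA1, a gap junction protein, by 0.58 (SE 0.12), KRT19 by 0.54 (SE 0.11) and the integrin gene ITGA6 by 0.43 (SE 0.09). With 4 arrays KRT15 stood at 1.82, GJA1 at 0.50, KRT19 at 0.18 and ITGA6 at -0.06. Cholesterol synthesis genes had a median of -0.13 with 4 arrays (adjusted p = 0.71) and 0.11 with 3 arrays (adjusted p = 0.027, and 0.88 with an estimated correlation), with HMGCS1 rising by 0.45 (SE 0.11) as 1 of 20 with 3 arrays. HMGCS1 stood at 0.07 with 4 arrays. The cholesterol call was lost with quantile normalization (adjusted p = 0.099) and without the dimmest 25% or 50% of genes (adjusted p = 0.074 and 0.19).

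Several lists were called with 4 arrays and not with 3. Interferon response genes had a median of -0.38 with 4 arrays (camera adjusted p = 0.00049, and 0.64 with an estimated correlation) and 0.03 with 3 arrays (adjusted p = 0.15), and scramble control replicate 1 lay 0.78 above the mean of the others. The siKLF7 arrays also differed: against scramble control replicate 2 the interferon median was 0.28 for siKLF7 replicate 1 and -0.15 for siKLF7 replicate 2. Without siKLF7 replicate 2 the interferon median was -0.25 and the call was lost. The mitochondrial respiratory chain had medians of 0.24 (adjusted p = 1.8e-05, and 0.64 with an estimated correlation) and 0.07 (adjusted p = 0.15), and with 3 arrays 0 of 36 members rose and 2 fell, also adjusted over the list alone. These were NDUFV2, a complex I subunit, by 0.70 (SE 0.15) and ATP5PB, an ATP synthase subunit, by 0.43 (SE 0.12; -0.23 with 4 arrays). Cell junction genes had medians of 0.20 (adjusted p = 0.043) and -0.02 (adjusted p = 0.77), heat shock proteins of 0.18 (adjusted p = 0.013) and 0.06 (adjusted p = 0.28), and glycolysis and hypoxia genes of 0.06 (adjusted p = 0.042) and -0.07 (adjusted p = 0.52). In the junction list with 3 arrays the test pointed up. With 3 arrays 1 of the 25 junction genes rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone. GJA1 rose by 0.58 (SE 0.12) and CLDN7, a tight junction protein, fell by 0.74 (SE 0.14). With 4 arrays the glycolysis call was also lost with quantile normalization (adjusted p = 0.14) and without the dimmest 25% or 50% of genes (adjusted p = 0.11 and 0.21), and the junction call with the same settings (adjusted p = 0.098, 0.17 and 0.46) and with median centring (adjusted p = 0.057). Without siKLF7 replicate 2 the glycolysis and junction calls were lost too (adjusted p = 0.093 and 0.13), and without the dimmest 50% of genes the heat shock call (adjusted p = 0.10). The glycolysis median lay within the range of 95% of random lists matched on mean level, -0.07 to 0.13. For the junction, heat shock and glycolysis lists too, the adjusted p with an estimated correlation was 0.64 with 4 arrays.

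All lists of markers of other cell types had medians below 0 with 4 arrays. Vascular endothelial markers had a median of -0.19 with 4 arrays (camera adjusted p = 0.0065, and 0.64 with an estimated correlation) and -0.16 with 3 arrays (adjusted p = 0.13). Leukocyte markers had medians of -0.15 (adjusted p = 0.040, and 0.64 with an estimated correlation) and -0.10 (adjusted p = 0.32). The vascular call was also lost without siKLF7 replicate 1 (median -0.11, adjusted p = 0.091) and without the dimmest 50% of genes (adjusted p = 0.13). The leukocyte call was lost with quantile normalization (adjusted p = 0.085), without scramble control replicate 2 (median -0.18, adjusted p = 0.056) and without siKLF7 replicate 1 (median -0.11, adjusted p = 0.39). Dim genes as a whole were lower, with a median of -0.13 with 4 arrays in bin 3 of 10 bins by mean level against 0.03 in bin 10, the brightest. The medians of the vascular and leukocyte lists lay within the range of 95% of 10000 random lists matched on mean level. Fibroblast and keratocyte markers had medians of -0.19 and -0.12, the first just below that range (lower bound -0.18) and the second within it, and LUM and POSTN, matrix proteins of these cells, rose by 0.64 (SE 0.16) and 0.86 (SE 0.18) with 3 arrays as 2 of 20. With 4 arrays POSTN stood at -1.18, and scramble control replicate 1 lay 3.50 above the mean of the others. LUM and POSTN were dim, with mean log2 levels of 6.30 and 6.23 in the siKLF7 arrays. The SD of POSTN in these arrays was 0.45 (n = 2). Melanocyte, conjunctival and goblet, neuronal and Schwann, and corneal endothelial markers had medians of -0.15, -0.09, -0.06 and -0.16 with 4 arrays and were not called in either fit.

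Lists tied to the targeted gene were not called by camera. The KLF and SP family had a median of -0.06 with 4 arrays (camera adjusted p = 0.70) and -0.05 with 3 arrays (adjusted p = 0.52), and KLF7 was the 1 of 25 members that fell with 3 arrays. KLF7 targets described in neurons had medians of 0.02 (adjusted p = 0.27) and 0.01 (adjusted p = 0.53). Fry's mixed test, for changes in either direction, called that list with 4 arrays (adjusted p = 0.0435). Of their 8 members, NTRK2 rose by 0.82 (SE 0.16) with 3 arrays, and it was the 1 that passed with 4 arrays adjusted over the list alone. NTRK2 was dim, with signals of 77.4 and 70.8 in the control arrays and 131 and 143 in the siKLF7 arrays. The cell cycle inhibitor gene CDKN1A stood at -0.32 (SE 0.11; -0.02 with 4 arrays) with 3 arrays, where it passed as lower adjusted over the list alone and not over all genes. Over the 30 lists, camera called 15 with 4 arrays and 7 with 3 arrays, and 5 in the same direction in both. With fry's directional test, 0 lists were called in either fit, the smallest adjusted p being 0.452 and 0.0896, and 2 lists had an unadjusted p under 0.05 in each. Fry's mixed test called 1 list in each fit, the KLF7 targets with 4 arrays and epidermal cornification with 3 arrays (adjusted p = 0.0198). With an estimated correlation 0 were called in either fit, and 1 list had an unadjusted p under 0.05 with 4 arrays. With few residual degrees of freedom that test could hardly call a list. It therefore does not tell whether correlation between genes made the camera calls.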

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

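With 4 arrays, the count of 0 genes by limma (1069 at an unadjusted p under 0.05) held under each normalization, filter, prior, pseudocount and threshold tried. Leaving out 1 array gave 0 to 4935 genes, the highest without scramble control replicate 2 and 290 without scramble control replicate 1. KLF7 ranged from -1.83 to -1.16 with 1 array left out, and passed only without one or the other control. Camera's count of 15 lists became 0 with an estimated correlation, 0 with fry's directional test and 7 to 18 with 1 array left out. Without scramble control replicate 1 the median and the test turned for corneal epithelial differentiation (-0.0665 to 3.40 over the arrays left out), differentiation regulators (-0.0840 to 0.84), interferon response (-0.78 to 0.0332) and glycolysis and hypoxia (-0.0737 to 0.31), and the median alone for epidermal cornification (-0.0322 to 2.49) and cell junctions (-0.0188 to 0.41). These turns follow from leaving out the array that lay apart from the other 3. With 3 arrays, the 290 genes became 461 with median centring (326 higher, 135 lower) and 172 with no intensity trend, and the 7 lists became 0 with an estimated correlation and 0 with fry's directional test. The cause of these was not tested. The 3-array settings were chosen after the data were seen. Of the other settings of single lists with 4 arrays, 197 kept call and direction and 54 lost the call. For named genes with 3 arrays, 179 kept both and 2 lost the call. Differences between replicates 1 and 2 correlated across genes at r = -0.041 between the groups. The control difference includes scramble control replicate 1, with 975 genes at least 2-fold apart against 14 in the siKLF7 pair. That array's departure could hide a link between equal replicate numbers, so whether the numbers mark a pairing is open. With a replicate block, 0 genes and 15 lists were called, and KLF7 kept its change of -1.50 (adjusted p = 0.735). The number of arrays limits the precision, and the pseudocount shrinks fold changes of dim genes.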

Other observations

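All tests of explanations here were chosen after the results were seen. With 3 arrays, genes of the extracellular matrix went both ways: SPARC and TGFBI, matrix proteins, rose by 0.63 (SE 0.11) and 0.53 (SE 0.11) against scramble control replicate 2, and the matrix metalloproteinase genes MMP1 and MMP10 fell by 0.79 (SE 0.16) and 0.59 (SE 0.16). With 4 arrays SPARC and TGFBI stood at 0.06 and 0.07, with scramble control replicate 1 above both siKLF7 arrays, and MMP1 and MMP10 at -2.58 and -0.98. These were 2 of 31 rising and 2 falling, and the list was not called in either fit (camera adjusted p = 0.18 with 4 arrays and 0.43 with 3). Among immediate early genes, EREG, an EGF receptor ligand, fell by 0.93 (SE 0.16) and MYC by 0.39 (SE 0.10), 2 of 22 (-1.97 and -0.38 with 4 arrays), and that list was not called (adjusted p = 0.49 and 0.15). Of the unfolded protein and integrated stress response genes, CHAC1 and CTH fell by 0.75 (SE 0.14) and 0.60 (SE 0.15) and HSP90B1, a chaperone of the endoplasmic reticulum, rose by 0.35 (SE 0.09). With 4 arrays CHAC1 and CTH stood at -0.06 and -0.03 and HSP90B1 at 0.25. That list was not called either (adjusted p = 0.30 and 0.073). The p53 target GDF15 fell by 0.70 (SE 0.14; 0.26 with 4 arrays) and the NRF2 list's ABCC3 by 0.60 (SE 0.16; -0.29 with 4 arrays), and HEY2 of the Wnt, Notch and TGF-beta list rose by 0.59 (SE 0.16; 0.31 with 4 arrays). None of these 3 lists was called.

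The genes that set scramble control replicate 1 apart were chosen by their values. The desmosomal cadherin DSG1 had a signal of 7.25 there and 3258 to 4485 in the other arrays, the keratin KRT10 13.0 against 2976 to 5959, and the metallothionein MT1H 23.7 against 4909 to 6913. Signals of DSG1 and KRT10 there were below the pseudocount of 16, so no fold is given. ANPEP, an aminopeptidase, had a signal of 6746 there and 86.6 to 88.7 in the others, the cytokine gene IL24 6341 against 108 to 143, and VCAN, a matrix proteoglycan, 2310 against 29.0 to 38.9.

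Several technical explanations for that array were weighed. Array scale is argued against, since 947 genes were at least 2-fold from the mean of the others after quantile normalization and 940 before. A label swapped with an siKLF7 array is argued against, since the siKLF7 arrays had 14 genes at least 2-fold apart and scramble control replicate 2 had 35 and 37 against them, so no array in the siKLF7 group was out of place. Dilution of the RNA by another cell type would lower basal epithelial markers too. Their median there was 0.17 (bootstrap interval over genes, -0.07 to 0.37) against -3.47 for differentiation genes. Of the 30 basal and limbal markers, 3 were at least 2-fold lower there, KRT15 at -2.50 among them, and 1 was at least 2-fold higher. That list also holds VIM and other genes not limited to epithelium, so its median argues against dilution only in part. The labels call all 4 samples undifferentiated, yet differentiation genes were higher in the other 3 arrays. KRT10, for example, had signals of 2976 to 5959 there and 13.0 in scramble control replicate 1. These values do not tell which arrays hold the labelled state. Cells of another state or origin, under that array's label or those of the other 3, may account for the distance and stay open. The 4-array values may therefore not compare the same cells. Beyond the check for mixed-up samples, no biological explanation was tested.

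For the higher level of mitotic genes in siKLF7 arrays, a shift that follows brightness is argued against: the highest median of 10000 random lists matched on mean level was 0.18 with 3 arrays, below the list's 0.39. Whether the state of scramble control replicate 2 alone may set it cannot be told apart from an effect of the knockdown. Against scramble control replicate 1 the list median was 0.15 with a bootstrap interval of -0.0008 to 0.22, and 25 of 39 members were higher. The interval resampled genes and not arrays, so it holds no spread between arrays. An effect of the knockdown stays open as a hypothesis.

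The 290 genes called with 3 arrays may in part reflect deviations of scramble control replicate 2. Of these, 190, or 65.5%, had the same sign against scramble control replicate 1, which shares the siKLF7 arrays: 117 of the 163 higher and 73 of the 127 lower genes. In 100 simulations with no effect the share was 46.9% to 64.5% when that array's departures were drawn from the called genes, and 60.3% to 74.5% when drawn from all genes of like level. With the fitted effects taken as true and departures drawn from the called genes, it was 68.3% to 80.7%. The observed share lay below all 100 of these, and above all with no effect and the same draw. It lay within the range with no effect when departures were drawn from all genes of like level. Fitted effects were not simulated with that draw. The 2 ways of drawing departures place the observed share differently, so an effect and deviations of scramble control replicate 2 cannot be told apart.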
